A study of Mus musculus with 71 samples.

How the data were processed

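Gene expression was measured in the cerebellum of WT mice and of Csbm/m mice, which carry a mutation in Csb, the protein product of Ercc6 and a model of Cockayne syndrome, on 71 Illumina MouseRef-8 v2 BeadChip arrays of 25697 probes each. Of these, 42 arrays belong to a diet experiment and 29 to a nicotinamide riboside (NR) experiment. The probe intensities on a linear scale were deposited as the non-normalized values, per the file headers, and the values show no sign of background subtraction. Beside each intensity the authors deposited a detection p-value for that probe on that array, per the file headers. The series values deposited by the authors are a score per probe with mean 0 and SD 1 on each array. That score equals the z-score of the log intensity of the same array to within 5e-10, which was found from the values, since no label states it. GenomeStudio 1.9.0 is the tool named per the labels. Its role, the background handling and the averaging of beads are not given in the sources used here.

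No 2 arrays held identical values (0 identical pairs). The highest correlation between 2 arrays was 0.996, and within groups correlations ran from 0.949 to 0.995. Each of 23978 probes carried 1 gene, 0 carried several and 1719 carried none in the annotation of the platform. Symbols were checked against RefSeq genes of GRCm38.p6, which changed 0 of them. That table served for names, chromosomes and the order of genes along a chromosome, and its coordinates are not printed. Among the probes analysed here 0 were assigned to Ercc6, so the labels could not be checked against the targeted gene, and its planned tests and alternatives were not run.

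Each experiment was normalized on its own with neqc from limma 3.58.1 in R 4.3.3 (normexp background correction from negative controls inferred from the detection p-values, offset 16, quantile normalization, log2), with data.table (1.17.8) and jsonlite 2.0.0. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Probes with a detection p under 0.05 on at least 3 arrays of the experiment were kept, 1 probe per symbol (that with the highest mean), which left 12611 genes in the diet experiment and 11595 in the NR experiment. A linear model with 1 mean per group (8 groups per experiment) was fitted with lmFit and eBayes, and every adjusted p is the two-sided moderated limma test with Benjamini-Hochberg adjustment over the genes tested, called at 0.05. Log2 changes are given with their SE and group levels with their SD. Where a gene was detected on no array of the lower group, its fold is a bound against the level that probes reach at a detection p of 0.05, written "at least". The labels number the replicates and do not say outright that each is another mouse. If some are not, the p-values measure only the spread between these samples, which may be technical.

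A total of 39 gene lists (pathways, stress responses and 12 sets of cell-type markers) was written before the data were examined, as were the comparisons, the alternatives and the rule for named genes. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, two-sided and adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. For each list the count of members passing over all genes and the count adjusted over the list alone were kept. The rule named the 8 highest and 8 lowest log2 changes among called genes with a symbol, the 3 members with the smallest p of each called list, and the 5 genes with the smallest p where fewer than 5 passed. For differences of differences and for the NR average it named the 5 smallest p. Among the genes fixed in advance were Bdh1, Oxct1, Slc16a1, Pdk4 and Angptl4 for the diets, and Nampt, Nmnat1, Nmrk1, Nnmt, Sirt1 and Parp1 for NR. Slc16a1 in the diet experiment and Nmnat1 in the NR experiment were not among the genes tested.

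Comparisons that share the Csbm/m standard-diet arrays were related to each other with those arrays split into 3 and 3, averaged over all splits, and with shared arrays beside 100 draws of arrays with no effect. Relations across experiments share no array and used exact permutation of the group labels, two-sided, with Benjamini-Hochberg adjustment over 7 relations. The mean level of the microglial list was compared between groups in 17 two-sided exact permutation tests, adjusted over the 17. For each count of called genes, up to 100 other splits of the same arrays were refitted.

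The labels give no BeadChip or date. Arrays were therefore clustered into 3 sets on 9052 probes detected on at most 10% of the 71 arrays, and this array batch was used for comparisons inside 1 batch. The clustering, the comparisons against caloric restriction and the genotype comparison on caloric restriction were chosen after the data had been seen. So were the stricter detection filter (detection p under 0.01), the fit without arrays of weight under 0.5, the fit without chromosome 14 genes, and the fit without replicate 2 of the NR-treated young Csbm/m group. Alternatives fixed in advance were no normexp step, the deposited score, no detection filter, every detected probe, eBayes with trend and robust, array weights, a block for the replicate number, Spearman correlation and each library left out in turn. The replicate numbers in the titles and the numbers in the sample names were checked for pairing. Every pair correlated above 0.1 in 3 of 16 comparisons for the title numbers (genotype in old saline mice, NR in old Csbm/m and NR in old WT) and in 0 of 8 for the name numbers. The pairing comes from these values, not from the labels.

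The fit was tested on simulated arrays, built from each gene's mean and residual SD with independent normal noise. In these, 200 genes were shifted by a known amount. They hold neither the batches and uneven libraries of the real arrays nor correlation between genes. The false calls below hold only for that setting. For the high-fat diet in Csbm/m (12611 genes), 56.1% of genes shifted by 0.5 log2, 91.0% at 1 and 98.5% at 2 were called, with 8 false calls. For NR in old Csbm/m (11595 genes) the shares were 28.8%, 89.6% and 98.5%, with 5 false calls. For the genotype in young saline mice (11595 genes) they were 27.3%, 86.6% and 100%, with 3 false calls, and for the genotype on the standard diet (12611 genes) 45.5%, 80.6% and 97.0%, with 9. A simulated shift of the microglial list by 0.5 log2 was called by camera in each of the 4 comparisons, and 1 of the 38 unshifted lists was called falsely in each of the 2 diet comparisons and 0 in the 2 NR comparisons.

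Intervals and bounds of the weighed explanations were changed after their results had been seen. For the standard-diet libraries set apart and the high-fat diet alone the first interval was a resampled mean over 20 overlapping draws (0.632 to 0.768 and -0.0812 to 0.0723), and the next the range over those draws (0.467 to 1.84 and -0.79 to 0.327). Shares of the batch and the genotype were first given their range with 1 array left out (0.44 to 0.658 and 0.279 to 0.385), and that of the array run its range over 20 splits (0.36 to 1.03). None of these is the spread between arrays, so each share is now given a delete-1 jackknife SE over arrays. An explanation counts as excluded where its value misses what it needs by over 2 SE, or, for Csbm/m mice under a WT label, in every library. The high-fat diet alone misses it too but is kept open. Its test needs resveratrol arrays free of an array run, which was not tested. All 5 values also meet the bounds first written for exclusion (under 0.2 or 0.25, or, for the standard-diet libraries and the array run, over 0.5). With 2 SE none of the 4 explanations of the high-fat change clears its written bound, while with the first interval the standard-diet libraries and the high-fat diet alone do. For the wrong label 1 library (0.281) lies past its bound.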

Results

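Expression was measured in whole cerebellum of male WT and Csbm/m mice on a C57BL/6 background. Csbm/m mice carry a mutation in Csb, a DNA-dependent ATPase that acts in transcription-coupled repair. Ercc6 encodes it. In the diet experiment mice aged 4 months were kept for 8 months on 1 of 4 diets. These were a standard diet with 17% of energy from fat, the same diet at 40% caloric restriction, the standard diet with 100 mg resveratrol per kg chow, and a high-fat diet made mainly with hydrogenated coconut oil (61% of energy from fat). The Csbm/m groups held 6 arrays on the standard diet, 6 on caloric restriction, 6 on resveratrol and 7 on the high-fat diet. The WT groups held 4, 4, 5 and 4. In the nicotinamide riboside (NR) experiment mice aged 4 or 18 months received NR, a precursor of NAD+, at 500 mg/kg per day, or saline, for 1 week. The young groups held 3 Csbm/m and 4 WT mice on NR and 3 and 4 on saline. The old groups held 4 and 5 on NR and 3 and 3 on saline. The share of probes detected per array was 55.1% to 63.4% (median 58.2%) in the diet experiment and 52.9% to 58.1% (median 54.8%) in the NR experiment. The 95th percentile of intensity lay 29.7 to 80.8 times above the array background in the former and 38.0 to 68.0 times in the latter. The number of arrays limits the precision of every comparison. Ercc6 itself was not analysed here, since 0 of the probes used were assigned to it, so no expression value checks the genotype labels.

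Arrays of the diet experiment fell into 2 batches when clustered on probes that were rarely detected. The first batch held 29 arrays, all 25 from Csbm/m mice and the 4 from WT mice on caloric restriction, and the second held the 13 other WT arrays. In the same clustering 1 array of the NR experiment, replicate 4 of NR-treated young WT, fell with the second. The mean correlation over those probes was 0.233 within the first batch, 0.243 within the second and -0.16 between them. H2-Q1, a class I histocompatibility gene near the detection limit, followed the batch: its log2 level was 6.92 ± 0.10 (SD, n = 4) in WT mice on caloric restriction and 6.99 to 7.10 in the Csbm/m groups, against 4.69 to 4.77 in the other WT groups. Genotype comparisons on the standard diet, on the high-fat diet, on resveratrol and over all diets therefore cross the batches, as do caloric restriction in WT and its difference between genotypes. The high-fat and resveratrol comparisons with the standard diet, within each genotype, and caloric restriction in Csbm/m stay inside 1 batch. Clustered again, the first batch has 2 sides: all standard-diet and caloric restriction arrays lie on 1 side, with 3 of 7 high-fat and 1 of 6 resveratrol arrays of Csbm/m. Resveratrol thus lies almost wholly across the sides, which was not tested for it.

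**Figure D1:**
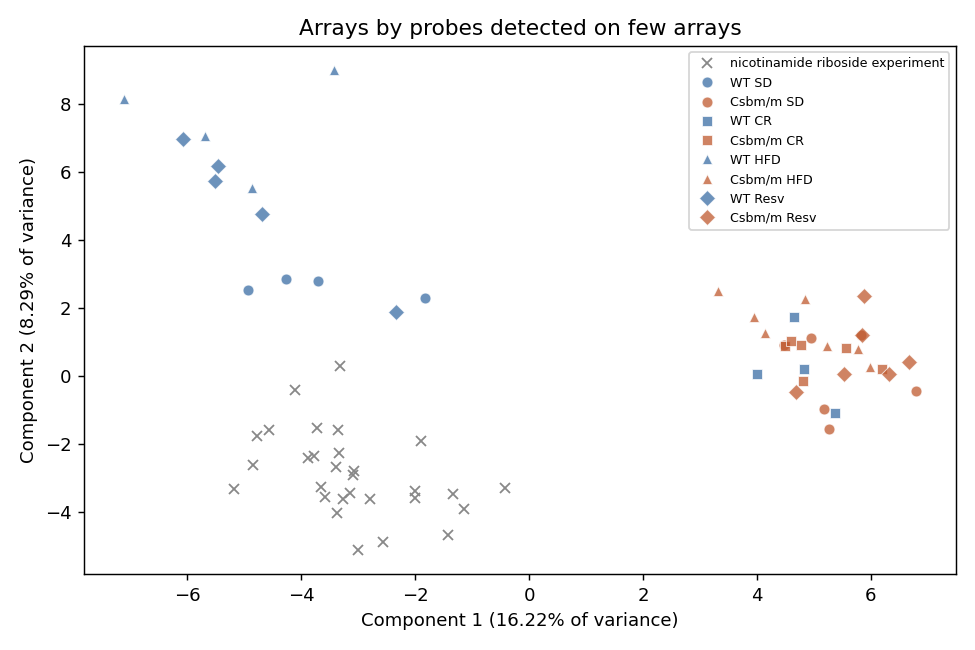
First 2 principal components of the 71 arrays over rarely detected probes (axes in percent of variance, 16.2% and 8.29%), with 1 point per array and group given by colour and marker. The 4 WT arrays on caloric restriction lie with the 25 Csbm/m arrays of the diet experiment, apart from the 13 other WT arrays.

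The first question was how the cerebellum of Csbm/m mice differs from that of WT mice at 1 year of age. The only genotype comparison inside 1 batch, on caloric restriction (6 against 4 arrays), was added after the data had been seen and is given first. Its groups differ in raw background, 75.6 ± 2.35 in Csbm/m (n = 6) against 59.2 ± 3.45 in WT (n = 4), so it is matched only in the cluster of arrays. Clec7a, a receptor carried by activated microglia, rose by 1.17 ± 0.22 log2 (adjusted p = 0.00546, higher in 6 of 6 arrays, its 3 other probes 0.13 to 0.73). The complement gene C4b rose by 0.99 ± 0.18 (adjusted p = 0.00449, 6 of 6) and the chemokine Ccl3 by 1.00, at least 1.43-fold (adjusted p = 0.0487). Among the lowest genes were Tmem254a at -1.69 ± 0.17 (adjusted p = 1.03e-08), Ncoa4, a receptor for the autophagy of ferritin, at -1.56 ± 0.13 (adjusted p = 5.01e-10), Plac9a at -1.42 ± 0.17 and Thap4 at -1.27 ± 0.12. Lum, a proteoglycan of connective tissue, fell by 1.19 ± 0.22 (-1.19, adjusted p = 0.00365). Gpd2, at -1.20 (adjusted p = 0.0165), is uncertain, since its other probe moved by 0.43. A total of 40 genes passed, 19 higher and 21 lower. Of these, 6 of the 38 with a known chromosome lie on chromosome 14, which carries Ercc6.

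In this batch-matched comparison 19 of the 22 microglial genes were higher in Csbm/m, 1 passing over all genes and 1 adjusted over the list alone (camera adjusted p = 0.00028). That list had an adjusted p = 0.773 with an estimated correlation. All 18 choroid plexus genes were lower (0 of 18 higher) with 0 passing singly (adjusted p = 1.82e-06, and 0.773 as an adjusted p with an estimated correlation). The 26 granule cell genes lay lower with 0 passing (adjusted p = 0.000128, and 0.889 as an adjusted p with an estimated correlation). The granule cell level was 0.95 and 0.23 in caloric restriction replicates 4 and 6 of Csbm/m and 1.85 to 2.46 in the other 4, against 1.95 to 2.34 in WT.

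On the standard diet (6 against 4 arrays) Clec7a rose by 1.40 ± 0.22 (adjusted p = 1.87e-05, 6 of 6 arrays higher). The microglial receptor Trem2 rose by 0.68 (adjusted p = 0.00373) and its adaptor Tyrobp by 0.69 (adjusted p = 0.0027). Tmem254a stood at 8.30 ± 0.37 (n = 6) against 10.18 ± 0.17 (n = 4), a change of -1.88 (adjusted p = 1.01e-10). Ncoa4 stood at 7.75 ± 0.18 against 9.55 ± 0.27, a change of -1.80 (adjusted p = 1.33e-12). The highest changes, H2-Q1 (2.30 ± 0.11, at least 3.62-fold), Fam83g (2.04), Agbl5 (1.79), Ppm1j (1.65) and Slc38a4 (1.56), were also called between WT mice on caloric restriction and on the standard diet, which also lie in different batches (H2-Q1 2.15, at least 3.28-fold, Ppm1j 1.61 and Slc38a4 1.47). Aqp1, a water channel of the choroid plexus, fell by 2.21 ± 0.71 (-2.21, adjusted p = 0.0308, 4 of 6 arrays below all WT arrays). Atf4, a transcription factor of the stress response, changed by -0.62 (adjusted p = 0.00716). The count was 1935 genes (1142 higher, 793 lower), against 40 in the batch-matched pair. It fell to 1122 without WT standard-diet replicate 4 and 1152 without replicate 3.

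Of the lists on the standard diet, 8 of 22 microglial genes rose (9 adjusted over the list alone, camera adjusted p = 0.00563, and 0.987 as an adjusted p with an estimated correlation). In the endoplasmic reticulum stress list 3 of 23 genes fell (3 adjusted over the list alone, adjusted p = 0.00592, and 0.6 as an adjusted p with an estimated correlation), among them Atf4 and the chaperones Pdia4 (-0.48) and Manf (-0.38). Meningeal and fibroblast genes fell in 9 of 23 cases (10 adjusted over the list alone, adjusted p = 0.00114, and 0.96 as an adjusted p with an estimated correlation), with Lum at -1.17 and the growth factor Igf2 at -0.97. Choroid plexus genes fell in 3 of 18 cases (3 adjusted over the list alone, adjusted p = 0.00114, and 0.987 as an adjusted p with an estimated correlation). Red blood cell genes fell in 2 of 6 (5 adjusted over the list alone, adjusted p = 0.00668, and 0.6 as an adjusted p with an estimated correlation), with Fech, the last enzyme of haem synthesis, at -0.63.

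On the high-fat diet (7 against 4 arrays) the complement genes C1qb (0.80 ± 0.12, adjusted p = 7.29e-06), C1qc (0.71) and C1qa (0.83) rose in Csbm/m, with Clec7a at 1.97 ± 0.21 (adjusted p = 1.16e-08, 7 of 7 arrays higher). Erdr1 (-2.44), Tmem254a (-1.60) and Klf10, a transcription factor induced by growth factors (-1.27, at least 1.60-fold, adjusted p = 8.22e-10), fell. Of 22 microglial genes 17 rose (17 adjusted over the list alone, camera adjusted p = 1.1e-13, and 0.104 as an adjusted p with an estimated correlation). Ribosomal protein genes rose in 13 of 42 cases (22 adjusted over the list alone, adjusted p = 1.17e-06, and 0.382 as an adjusted p with an estimated correlation), with Rpsa at 0.80. Complexes II to V of the respiratory chain rose in 8 of 38 (9 adjusted over the list alone, adjusted p = 0.00123, and 0.542 as an adjusted p with an estimated correlation). The count was 1624 genes (954 higher, 670 lower), and 870 without WT high-fat replicate 1. This comparison too crosses the batches. Averaged over all 4 diets, 4856 genes passed (2453 higher, 2403 lower). Among immune genes Clec7a led at 1.58 ± 0.11, with Gpnmb, a marker of phagocytic cells, at 1.25 ± 0.10 and the chemokine Ccl4 at 1.24. Of 22 microglial genes 17 rose over all diets (18 adjusted over the list alone, adjusted p = 1.69e-09, and 0.413 as an adjusted p with an estimated correlation). Cox4i1, a respiratory chain gene at 0.22, turned to -0.02 with the deposited score.

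The mean level of the microglial list, tested two-sided with each array as 1 value, was higher in Csbm/m than in WT in each of the 4 diet pairs. It was 0.68 ± 0.21 (n = 6) against 0.38 ± 0.12 (n = 4) on the standard diet (exact permutation p = 0.0286, adjusted 0.06). It was 0.29 ± 0.09 against 0.06 ± 0.16 on caloric restriction, inside 1 batch (exact permutation p = 0.0286, adjusted 0.06). On the high-fat diet it was 0.79 ± 0.17 (n = 7) against 0.07 ± 0.16 (n = 4; exact permutation p = 0.00303, adjusted 0.0103). On resveratrol it was 0.83 ± 0.11 (n = 6) against 0.23 ± 0.24 (n = 5; exact permutation p = 0.00217, adjusted 0.0092). Among the diet pairs only those on the high-fat diet and resveratrol passed after adjustment. Like the standard-diet pair they cross the batches, so genotype and batch cannot be told apart in them. In the NR experiment the level was 0.16 ± 0.27 (n = 3) against -0.81 ± 0.18 (n = 4) in young saline mice (exact permutation p = 0.0286, the smallest that design allows, adjusted 0.06). In old saline mice it was 0.62 ± 0.39 against -0.18 ± 0.39 (n = 3 each; exact permutation p = 0.1, the smallest allowed), with pair differences of 0.70 to 0.92 (exact permutation of signs p = 0.25, the smallest for 3 pairs). In NR-treated mice the level was -0.08 ± 0.85 against -0.54 ± 0.21 in the young (n = 3 and 4; exact permutation p = 0.343, adjusted 0.37), where Csbm/m replicate 2, whose label is in doubt, lay at -1.06 and the other 2 at 0.46 and 0.37, and 0.39 ± 0.12 against -0.20 ± 0.37 in the old (n = 4 and 5; exact permutation p = 0.0318, adjusted 0.06).

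**Figure D2:**
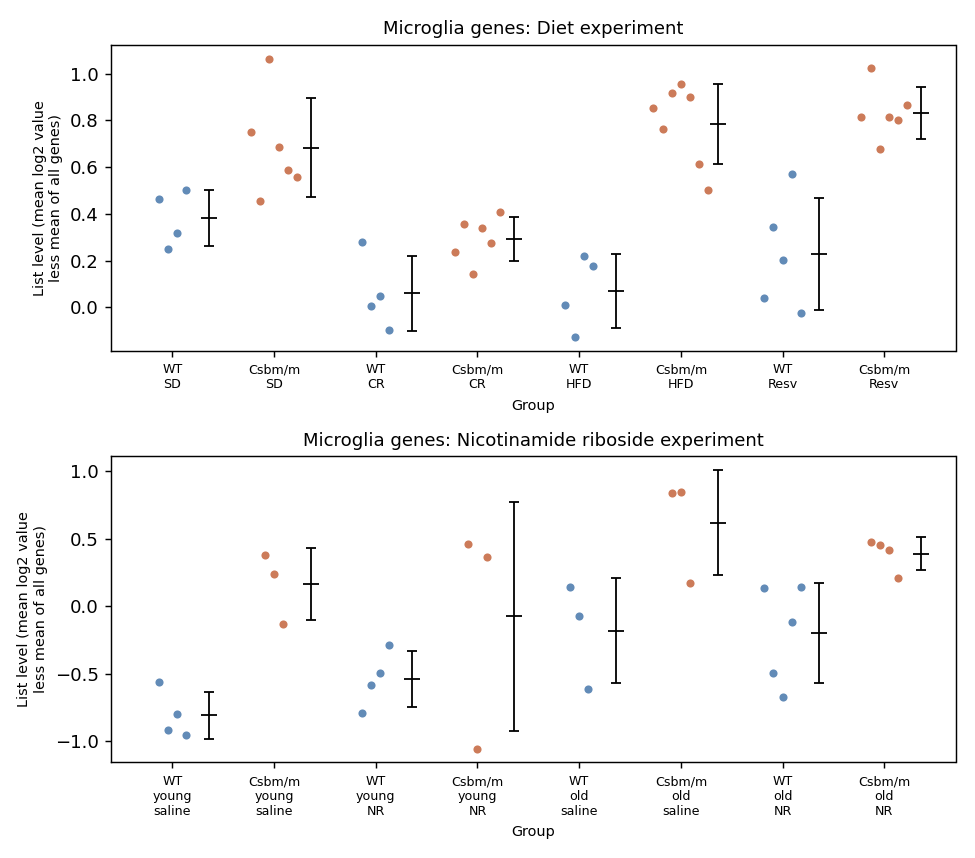
Mean log2 level of the 22 microglial genes less the mean of all genes tested on the same array (y axis), in each group of the diet and NR experiments (x axis), with points for arrays and a black bar for mean ± SD. In Csbm/m mice caloric restriction gives 0.29 ± 0.09 (n = 6) against 0.68 ± 0.21 on the standard diet (n = 6).

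The next question, the centre of the study's title, was what a high-fat diet does to the Csbm/m cerebellum. Against the standard diet (7 against 6 arrays) some genes of granule neurons rose. The GABA receptor subunit Gabra6 went from 8.19 ± 2.28 to 10.79 ± 0.52, a rise of 2.61 ± 0.83 (adjusted p = 0.0317, 5 of 7 arrays above all controls). The transcription factor Neurod1 rose by 2.22 ± 0.61 (adjusted p = 0.0136). Ppp1r17, a phosphatase inhibitor of Purkinje cells, rose by 1.97 ± 0.60 (adjusted p = 0.0258). The respiratory chain genes Atp5e (0.70 ± 0.13, adjusted p = 0.00104, 7 of 7 arrays), Cox7b (0.75) and Sdhd (0.57) rose, as did the class II histocompatibility gene H2-Aa (0.96 ± 0.19, adjusted p = 0.00146, 7 of 7). Vgf, the precursor of neuronal peptides, fell by 1.53 ± 0.27 (-1.53, adjusted p = 0.000808, 6 of 7 below all controls) and Pip5kl1 by 1.25 ± 0.19 (-1.25, 7 of 7). The transcription factor Isl1 fell by 1.45 (-1.45, adjusted p = 0.0292) and the heat shock protein Hspa1a by 1.24 (-1.24, adjusted p = 0.00545). Of the ketone body enzymes, Bdh1 moved by 0.24 (adjusted p = 0.315) and Oxct1 by -0.08 (adjusted p = 0.394). Of the targets of fatty acid signalling, Pdk4 moved by -0.57 (adjusted p = 0.118) and Angptl4 by 0.12 (adjusted p = 0.74).

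In this comparison 11 of 23 meningeal genes rose and 1 fell (16 and 1 adjusted over the list alone, camera adjusted p = 2.01e-06, and 0.504 as an adjusted p with an estimated correlation). Granule cell genes rose in 6 of 26 cases (9 adjusted over the list alone, adjusted p = 2.14e-05) and choroid plexus genes in 3 of 18 (8 adjusted over the list alone, adjusted p = 2.14e-05), each with 0.504 as an adjusted p with an estimated correlation. The granule cell level was 0.33 and 0.06 in standard-diet replicates 1 and 3, 1.56 to 2.18 in the other 4 and 1.67 to 2.41 on the high-fat diet. Choroid plexus levels were low in standard-diet replicates 1, 4 and 6. Complexes II to V rose in 8 of 38 cases (8 adjusted over the list alone, adjusted p = 0.0395, and 0.59 as an adjusted p with an estimated correlation). Histone genes rose in 4 of 19 with 1 lower (11 and 1 adjusted over the list alone, adjusted p = 3.11e-05, and 0.504 as an adjusted p with an estimated correlation). A total of 1723 genes passed, 733 higher and 990 lower. The standard-diet group was uneven (Gabra6 SD 2.28 there against 0.52), and the count was 876 without its replicate 3 and 1113 without high-fat replicate 6. Against caloric restriction as the control, added after the data had been seen, the high-fat diet gave 224 genes.

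In WT mice the high-fat diet gave 28 genes (23 higher, 5 lower; 4 against 4 arrays). Klf10 rose by 1.12 ± 0.14, at least 1.91-fold (adjusted p = 8.94e-06), Akap8, an anchor of protein kinase A, by 0.84 (adjusted p = 0.00531) and the actin-binding Cnn3 by 0.71 (adjusted p = 0.0112). Gng10 (-0.68), a G protein subunit, and the mitochondrial ribosomal gene Mrpl22 (-0.54) fell. Microglial genes lay lower as a list with 0 passing over all genes and 5 adjusted over the list alone (camera adjusted p = 5.78e-05, and 0.906 as an adjusted p with an estimated correlation). In all 7 lists were called, 0 of them with an estimated correlation. Purkinje cell, granule cell, choroid plexus and histone lists were the 4 higher ones. WT standard-diet replicate 1 stood apart in Purkinje cell level (0.12, others 1.29 to 1.43). The count ranged from 2 without WT high-fat replicate 1 to 86 without replicate 2, and it was 341 with the deposited score, in which 48.7% of called genes were higher against 82.1%.

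The diet effect itself was compared between genotypes. The change with the high-fat diet in Csbm/m minus that in WT passed for 61 genes, 15 higher and 46 lower, led by Klf10 (-1.11 ± 0.17, adjusted p = 0.0023), Gm12657 (1.17 ± 0.21, adjusted p = 0.00944), the polarity gene Scrib (-1.34), the elongation factor Eef1a2 (-0.83) and Clasrp (-0.99). The ribosomal list stood higher in this difference with 1 of 42 passing (2 adjusted over the list alone, camera adjusted p = 1.75e-06, and 0.362 as an adjusted p with an estimated correlation). Without single libraries the count ran from 9 (WT high-fat replicate 1) to 318 (WT standard-diet replicate 1).

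Whether the high-fat diet moves genes opposite to the genotype was asked across genes. With the Csbm/m standard-diet arrays split between the comparisons, the mean correlation of the log2 changes was -0.27 (-0.48 to -0.03 over the splits), where arrays with no effect gave 0.0449 (-0.39 to 0.46). With shared arrays it was -0.53, with a covariance of -0.0628 against -0.0155 with no effect (mean correlation -0.42, range of 95% of draws -0.76 to 0.0231). The batch-matched genotype change on caloric restriction, which shares no array with the high-fat change, gave -0.56 (no effect: -0.44 to 0.40). The same split gave -0.08 with caloric restriction and -0.23 with resveratrol in place of the high-fat diet, and -0.60 for resveratrol against the batch-matched pair. Some restricted and some standard-diet libraries of Csbm/m had low granule cell levels, as given above. These lower the batch-matched genotype change and raise the high-fat and resveratrol changes in the same genes. Their part in the correlations was not tested. Genes are not independent replicates.

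Caloric restriction, the opposite change in energy intake, was examined next. In Csbm/m (6 against 6 arrays) Fcrls, a receptor of homeostatic microglia, fell from 7.86 ± 0.54 to 6.31 ± 0.34, by 1.55 ± 0.22 (-1.55, adjusted p = 0.000142, 6 of 6 arrays). Gpnmb fell by 1.08 ± 0.18 (-1.08, adjusted p = 0.00139, 4 of 6 below all controls) and C1qb by 0.56 (-0.56, adjusted p = 0.0167, 6 of 6). Wfdc18 (-1.64), the uridine phosphorylase Upp2 (-1.40), and Oxct1, which admits ketone bodies to oxidation (-0.32, adjusted p = 0.0257), also fell. The actin regulator Cfl1 (0.81 ± 0.16, adjusted p = 0.0206) and Acat1, a thiolase of ketone metabolism (0.58 ± 0.12, adjusted p = 0.0404), rose. These are 8 of 11 genes that passed, 2 higher and 9 lower. Of 22 microglial genes 2 fell (11 adjusted over the list alone), with 2 of 22 higher, and the list passed with both camera settings (adjusted p = 8.27e-15, and 0.0365 as an adjusted p with an estimated correlation). The 6 red blood cell genes all lay higher, 0 passing singly and 5 adjusted over the list alone, and this list also passed both (adjusted p = 1.17e-08, and 0.0114 as an adjusted p with an estimated correlation). Slc4a1, the red cell anion exchanger, stood at 2.07 (adjusted p = 0.064).

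Glucocorticoid response genes lay lower in restricted Csbm/m mice, with 0 of 25 passing and 5 adjusted over the list alone (camera adjusted p = 2.87e-05, and 0.544 as an adjusted p with an estimated correlation). Complement and antigen presentation genes fell in 1 of 16 cases, C1qb (6 adjusted over the list alone, adjusted p = 3.65e-05, and 0.241 as an adjusted p with an estimated correlation). The microglial level itself was lower on caloric restriction than on the standard diet by 0.39 (difference -0.39, exact permutation p = 0.00217, the smallest for 6 against 6, adjusted 0.0092). It stood 0.49 higher on the high-fat diet (exact permutation p = 0.00117, adjusted 0.0092) and 0.54 higher on resveratrol (exact permutation p = 0.00217, adjusted 0.0092) than on caloric restriction. Against the standard diet the high-fat diet (0.10, exact permutation p = 0.349) and resveratrol (0.15, exact permutation p = 0.162) did not shift it detectably. The count of 11 genes became 6 without caloric restriction replicate 2 or 5, 18 without standard-diet replicate 1 and 28 without replicate 4. It was 45 with array weights.

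In WT mice caloric restriction gave 576 genes (436 higher, 140 lower; 4 against 4 arrays), but it crosses the batches. Fcrls fell by 1.69 ± 0.27 (-1.69, adjusted p = 3.83e-05), Wfdc18 by 1.28 (-1.28, adjusted p = 0.00476) and C1qb by 0.53 (-0.53, adjusted p = 0.0123), each in 4 of 4 arrays. Map3k6, a stress kinase, fell by 1.19 (-1.19, adjusted p = 0.0284). Microglial genes fell in 2 of 22 cases (3 adjusted over the list alone, camera adjusted p = 0.00112, and 0.866 as an adjusted p with an estimated correlation). The difference between genotypes passed for 245 genes, 20 higher and 225 lower, led by H2-Q1 (-2.22) and Fam83g (-2.07), which follow the batch. Fcrls, by contrast, moved in the same direction in both genotypes.

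**Figure D3:**
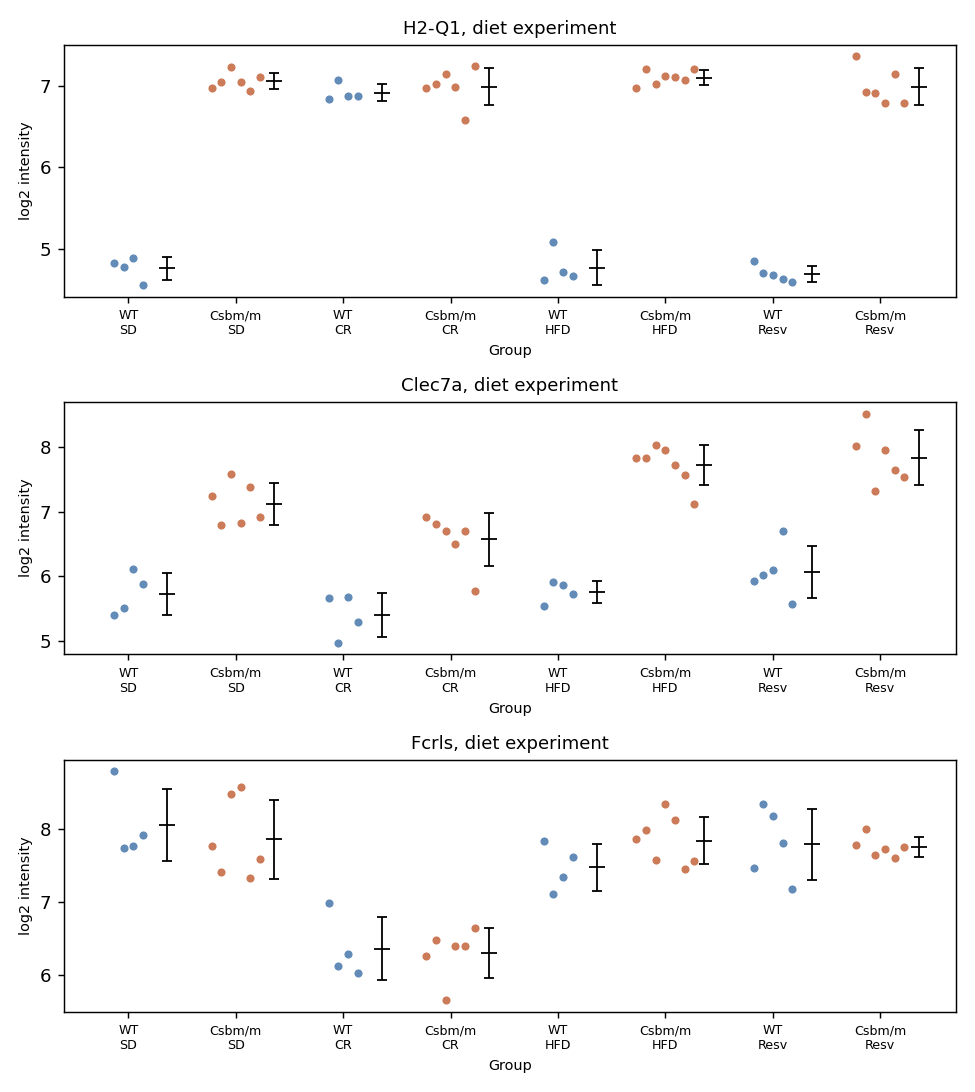
Log2 levels (y axis) of H2-Q1, Clec7a and Fcrls in the 8 groups of the diet experiment (x axis), with points for arrays (blue WT, orange Csbm/m) and a black bar for mean ± SD. Fcrls lies at 6.31 ± 0.34 and 6.36 ± 0.43 under caloric restriction and at 7.48 to 8.05 in the other groups, while H2-Q1 is high in WT only on caloric restriction.

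Resveratrol was given to ask whether a compound linked to sirtuin activity acts on the mutant cerebellum. In Csbm/m (6 against 6 arrays) Gabra6 (2.69 ± 0.86, adjusted p = 0.0391), Neurod1 (2.28 ± 0.63, adjusted p = 0.0178) and Ppp1r17 (2.08 ± 0.62) rose, with the choroid plexus genes Folr1 (2.17 ± 0.66, adjusted p = 0.031), a folate receptor, and Kcne2 (2.21 ± 0.68), a potassium channel subunit. The tricarboxylic acid cycle gene Sucla2 (1.00 ± 0.23, adjusted p = 0.00514), the respiratory chain gene Cox7b (0.99 ± 0.18, adjusted p = 0.00102) and the astrocyte gene S100b (1.00 ± 0.23) also rose. The synaptic gene Nptx2 (-2.08 ± 0.52, adjusted p = 0.0104), the transcription factors Gata3 (-2.07) and Bcl11b (-1.63), and the dopamine receptor Drd1 (-1.64 ± 0.52, adjusted p = 0.0367) fell. Complexes II to V rose in 10 of 38 cases (11 adjusted over the list alone, camera adjusted p = 0.000483, and 0.406 as an adjusted p with an estimated correlation). Choroid plexus genes rose in 7 of 18 (14 adjusted over the list alone, adjusted p = 2.14e-07, and 0.406 as an adjusted p with an estimated correlation). Granule cell genes rose in 6 of 26 (9 adjusted over the list alone, adjusted p = 2.83e-05, and 0.422 as an adjusted p with an estimated correlation). Controls stood apart in both lists: granule cell levels were 0.33 and 0.06 in standard-diet replicates 1 and 3 (the other 4 at 1.56 to 2.18, resveratrol 1.80 to 2.29), and choroid plexus levels -1.69, -1.60 and -1.60 in replicates 1, 4 and 6. In all 1298 genes passed (582 higher, 716 lower). The count was 795 without standard-diet replicate 3 and 821 without resveratrol replicate 2, and 206 against caloric restriction as control.

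In WT mice limma called 0 genes with resveratrol, and 931 had an unadjusted p under 0.05 (5 against 4 arrays). The smallest p belonged to Klf10 (0.60 ± 0.13, adjusted p = 0.391). A single gene passed for the difference between genotypes, Gm12657 (1.14 ± 0.21, adjusted p = 0.0366), and that count was 0 without any of 12 single libraries and 119 without WT standard-diet replicate 1.

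The high-fat and resveratrol changes in Csbm/m were close to each other: 0 genes separated the 2 diets in limma (440 with an unadjusted p under 0.05). With split controls their correlation across genes was 0.55 (0.34 to 0.73; no effect -0.44 to 0.43). With shared controls it was 0.87 with a covariance of 0.0980, where arrays with no effect gave a mean of 0.47 and a covariance of 0.0152. Against caloric restriction the complement list rose in 6 of 16 cases on the high-fat diet (11 adjusted over the list alone, camera adjusted p = 2.42e-12, and 0.0124 as an adjusted p with an estimated correlation). With resveratrol it rose in 6 of 16 (12 adjusted over the list alone, adjusted p = 6.72e-11, and 0.025 as an adjusted p with an estimated correlation), but over the same 6 restricted arrays, so these 2 rises do not speak for a shared change.

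The NR experiment repeats the genotype comparison at 4 months and at 18 months. In young saline mice (3 against 4) Clec7a rose by 2.46 ± 0.46, at least 3.81-fold (adjusted p = 0.0272, 3 of 3 arrays), and Gpnmb by 2.24 ± 0.40 (adjusted p = 0.0174, 3 of 3). Arhgap22, a GTPase regulator 14 genes from Ercc6, rose by 1.78 ± 0.31 (adjusted p = 0.0174). Ncoa4 (-2.13 ± 0.28, adjusted p = 0.000638), Tmem254a (-1.87 ± 0.26, adjusted p = 0.000638) and Plac9a (-1.94 ± 0.32, adjusted p = 0.0105) fell. Plac9a was detected on 1 of 3 Csbm/m arrays, so the size of its change is uncertain. That makes 6 genes, of which 4 lie on chromosome 14. Of 22 microglial genes 1 rose over all genes and 16 adjusted over the list alone, with 21 of 22 higher, and the list passed both camera settings (adjusted p = 1.06e-34, and 0.0205 as an adjusted p with an estimated correlation). Complement and antigen presentation genes did so too (17 of 17 higher, 0 passing, 4 adjusted over the list alone, adjusted p = 2.14e-15, and 0.0205 as an adjusted p with an estimated correlation). Lysosome and autophagy genes passed both as well (0 of 35 passing and 0 adjusted over the list alone, adjusted p = 0.0128, and 0.0318 as an adjusted p with an estimated correlation). Brainstem and midbrain markers also lay higher, 0 of 29 passing and 6 adjusted over the list alone (adjusted p = 1.36e-11, and 0.315 as an adjusted p with an estimated correlation). Their level was -2.68 to -0.72 in WT and -1.48 to -0.52 in Csbm/m. In WT the microglial level was highest (-0.56, replicate 1) and lowest (-0.96, replicate 4) where the brainstem level was. Csbm/m replicate 3 had a lower brainstem level than WT replicate 1 but a higher microglial level (-0.13). Whether the tissue sampled differed was not tested, so its part in the microglial rise is open. Interferon response genes lay higher too (0 of 25 passing, 1 adjusted over the list alone, adjusted p = 1.04e-11, and 0.0598 as an adjusted p with an estimated correlation). In all 14 lists were called, 9 of them higher. Astrocyte, oligodendrocyte and choroid plexus lists were also higher, and Purkinje cell, granule cell and synapse lists lower. WT replicate 4 stood apart in choroid plexus level (-2.15, others -0.78 to 0.35). The count of 6 became 2 without Csbm/m replicate 3, and 3 without Csbm/m replicate 1 or 2 or WT replicate 2, 3 or 4.

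In old saline mice (3 against 3) Gpnmb rose by 3.41 ± 0.43 (adjusted p = 5.19e-05) and the galectin Lgals3 by 2.52 ± 0.39 (adjusted p = 0.000824). The inhibitory Fc receptor Fcgr2b rose by 1.83 (adjusted p = 0.00381, though another of its probes moved by -0.06), C4b by 1.82 ± 0.41 (adjusted p = 0.0438) and the cystatin Cst7 by 1.08 (adjusted p = 0.0405), each in 3 of 3 arrays. Ang, a secreted ribonuclease (2.65, at least 5.04-fold), Samd4 (2.32) and the proteasome subunit Psmb5 (1.61) stood higher as well, all on chromosome 14, which also carries Lgals3. For these 3 genes the old WT saline group stands apart, not Csbm/m. Samd4 was 6.66 there, 8.98 in old Csbm/m on saline and 9.02 in old WT on NR. In the same order Psmb5 was 8.67, 10.28 and 9.82, and Ang 5.025, 7.67 and 6.79. Tmem254a fell by 1.31 (-1.31, adjusted p = 0.0302). Lysosome and autophagy genes lay higher with 0 of 35 passing (3 adjusted over the list alone, camera adjusted p = 0.00215, and 0.0215 as an adjusted p with an estimated correlation). Microglial genes rose in 1 of 22 cases (14 adjusted over the list alone, adjusted p = 2.32e-10, and 0.42 as an adjusted p with an estimated correlation). Granule cell genes lay lower, 0 of 25 passing (4 adjusted over the list alone, adjusted p = 1.15e-08, and 0.552 as an adjusted p with an estimated correlation). Brainstem (0 of 29 passing, 1 adjusted over the list alone, adjusted p = 3.75e-05), choroid plexus (0 of 18 and 0, adjusted p = 0.0274) and glucocorticoid response genes (0 of 24 and 0, adjusted p = 0.000788) lay higher, with 0.735, 0.77 and 0.735 as adjusted p with an estimated correlation. WT replicate 3 stood apart in 4 of these levels (brainstem -2.37, choroid plexus -1.97, granule cell 2.42, microglia -0.61), and Csbm/m replicate 3 in 2 (glucocorticoid 2.30, microglia 0.17). Complex I, complexes II to V and ribosomal lists were also called higher. WT replicate 3 was lowest in them too (complex I 2.98 against 3.26 and 3.49, ribosomal 3.70 against 3.97 and 4.22 in the other WT). In all 44 genes passed (37 higher, 7 lower). The count was 12 without WT replicate 3, 18 without WT replicate 2, 22 without Csbm/m replicate 3 and 24 without Csbm/m replicate 2. Across 11501 genes the genotype change in young and old saline mice correlated at 0.48 (exact permutation p = 0.1, the smallest allowed, adjusted 0.175). The standard-diet change correlated with them at 0.10 (exact permutation p = 0.4, adjusted 0.56) and 0.24 (exact permutation p = 0.1, the smallest allowed). The batch-matched change on caloric restriction did so at 0.17 (exact permutation p = 0.629) and 0.40 (exact permutation p = 0.1, the smallest allowed).

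Age was compared in saline mice. In WT (3 old against 4 young) the cathepsin Ctss of microglia rose by 1.38 ± 0.29 (adjusted p = 0.0221), the adhesion molecule Icam1 by 1.14 ± 0.24 (adjusted p = 0.0221) and the respiratory gene Sdhd by 0.92 ± 0.18 (adjusted p = 0.0137). The cell cycle inhibitor Cdkn1b fell by 1.75 ± 0.28 (-1.75, adjusted p = 0.00114) with Zic2, a granule cell factor (-1.49, adjusted p = 0.0293). In Csbm/m (3 against 3) Ctss (1.49 ± 0.31, adjusted p = 0.018), Gpnmb (1.74 ± 0.43, adjusted p = 0.0356) and Sdhd (1.20 ± 0.20, adjusted p = 0.00372) rose and Cdkn1b (-1.92 ± 0.29, adjusted p = 0.00257) and Zic2 (-1.84) fell. The dopamine transporter Slc6a3 (5.20 ± 1.17, adjusted p = 0.0264, detected on 1 of 3 young arrays), tyrosine hydroxylase Th (adjusted p = 0.0115) and urocortin, Ucn (2.96, at least 5.38-fold), genes of midbrain neurons, stood higher beside them. All 3 belong to the list of brainstem and midbrain neighbours of the cerebellum. The level of that list was -1.48 to -0.52 in young and -0.32 to -0.05 in old Csbm/m on saline. Whether the tissue sampled differed was not tested. The counts were 104 in WT (42 higher, 62 lower), with Samd4 (-2.96) and Ncoa4 (-1.83) on chromosome 14 among the lowest, and 255 in Csbm/m (144 higher, 111 lower). The former ran from 19 (without old replicate 2) to 185 (without old replicate 1) and the latter from 14 (without young replicate 2) to 459 (without old replicate 1).

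Granule cell genes fell with age in 5 of 25 cases in Csbm/m (9 adjusted over the list alone, camera adjusted p = 6.32e-08, and 0.53 as an adjusted p with an estimated correlation) and in 1 of 25 in WT (1 adjusted over the list alone, adjusted p = 0.0158, and 0.735 as an adjusted p with an estimated correlation). Brainstem markers rose in 3 of 29 cases in Csbm/m (6 adjusted over the list alone, adjusted p = 0.00477, and 0.743 as an adjusted p with an estimated correlation). Interferon response genes rose in 2 of 25 cases in Csbm/m, Trim30a (1.17) and the immunoproteasome subunit Psmb8 (0.71), with 13 adjusted over the list alone (adjusted p = 7.63e-07, and 0.383 as an adjusted p with an estimated correlation). In WT 0 of 25 passed and 4 adjusted over the list alone (adjusted p = 2.28e-06, and 0.285 as an adjusted p with an estimated correlation). The change with age differed between genotypes for 4 genes, Samd4 (2.41), Apex1, a base excision repair nuclease (1.32), Ang (2.14) and Ogfod3 (1.22), and 3 of these lie on chromosome 14. All 4 were lowest in old WT on saline among the 8 groups.

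The last question was whether NR, given to raise NAD+, changes the mutant cerebellum. In old Csbm/m mice (4 against 3) 1 gene passed: Cxcl13, a chemokine for B cells, fell by 1.03 ± 0.16 (-1.03, at least 1.67-fold, adjusted p = 0.014, 4 of 4 arrays below all controls), to a level at which it was not detected. This call was lost without NR replicate 2 or 4 or saline replicate 2 or 3 (0 genes each), without normexp and with the deposited score, and 13 genes passed without saline replicate 1. The NAD+ genes moved by -0.49 (Nampt, adjusted p = 0.491), -0.00 (Nmrk1), -0.42 (Nnmt, adjusted p = 0.518), 0.05 (Sirt1) and 0.27 (Parp1, adjusted p = 0.522). Granule cell genes lay higher with 0 of 25 passing and 3 adjusted over the list alone (camera adjusted p = 7.4e-07). Brainstem markers lay lower with 0 of 29 passing and 2 adjusted over the list alone (adjusted p = 0.00234) and so did ribosomal genes with 0 of 41 passing and 0 adjusted over the list alone (adjusted p = 0.00032). All 3 had 0.81 as an adjusted p with an estimated correlation. The microglial level moved by -0.23 (exact permutation p = 0.286). The NR change in old Csbm/m correlated with the genotype change on the standard diet at -0.28 (11501 genes, exact permutation p = 0.0857, adjusted 0.175), and in young Csbm/m at 0.000751 (exact permutation p = 1).

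In young Csbm/m mice (3 against 3) limma called 0 genes with NR, and 87 had an unadjusted p under 0.05. The smallest p belonged to Gpd2 (1.66), Dus2 (0.50), Dusp2 (0.51), Washc2 (-0.62) and Insig2 (0.55), each with an adjusted p of 1. In young WT (4 against 4) limma also called 0, with 688 at an unadjusted p under 0.05, led by Zbtb7b (-0.72, adjusted p = 0.0544) and Tmem267 (1.23, adjusted p = 0.0544). All 18 choroid plexus genes lay higher there, 0 passing and 5 adjusted over the list alone (camera adjusted p = 5.34e-13, and 0.593 as an adjusted p with an estimated correlation). The level was -2.15 in saline replicate 4 and -0.78 in replicate 2, and -0.24 to 0.68 on NR. Nampt moved by -0.07 in young Csbm/m and by 0.16 (adjusted p = 0.917) in young WT. The library labelled replicate 2 of NR-treated young Csbm/m lay near WT at Ncoa4 (8.91, others 7.29 and 7.43), Gpnmb (7.37, others 10.26), Clec7a (5.02, others 7.72 and 7.80), Thap4 (9.28) and Entpd4 (12.55), and nearer Csbm/m at Tmem254a (8.23) and Plac9a (5.66). Without it limma also called 0 genes with NR in young Csbm/m.

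In old WT mice (5 against 3) 8 genes rose with NR, each in 5 of 5 arrays: Samd4, a repressor of translation, by 2.36 ± 0.18 (adjusted p = 4.48e-09), Ncoa4 by 2.12 ± 0.27, Ang by 1.76 ± 0.25 (at least 2.73-fold), Ogfod3 by 1.36 ± 0.15, Psmb5 by 1.15 ± 0.21, Tmem260 by 1.11 ± 0.14, Apex1 by 1.04 ± 0.11 (another probe moved by -0.04) and Abhd4 by 0.97 ± 0.13. Of these, 7 lie on chromosome 14. The saline group is the one that stands apart: Samd4 was 6.66 ± 0.23 in old WT on saline (n = 3) and 8.98 to 9.62 in all 7 other groups. Complex I genes lay lower with 0 of 33 passing and 13 adjusted over the list alone (camera adjusted p = 6.62e-17, and 0.535 as an adjusted p with an estimated correlation). The complex I level was 2.08 to 2.66 in NR replicates 2 to 4, but 3.51 and 3.13 in replicates 1 and 5 and 2.98 to 3.49 on saline. Ribosomal levels were low in the same 3 libraries (3.03 to 3.40, against 3.70 to 4.22 on saline). The count was 207 without NR replicate 1. The difference between genotypes passed for Samd4 (-2.24), Apex1 (-1.18), Abhd4 (-1.19) and Ang (-2.23), all on chromosome 14, and Samd4 (0.61), Tmem267 (0.67) and Ogfod3 (0.41) passed over all NR groups. Samd4 and Ogfod3 owe this to old WT, since Samd4 moved by -0.09 to 0.12 and Ogfod3 by 0.00 to 0.26 in the other 3 groups. That count of 3 became 1 when any of 21 libraries was left out singly.

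**Figure D4:**
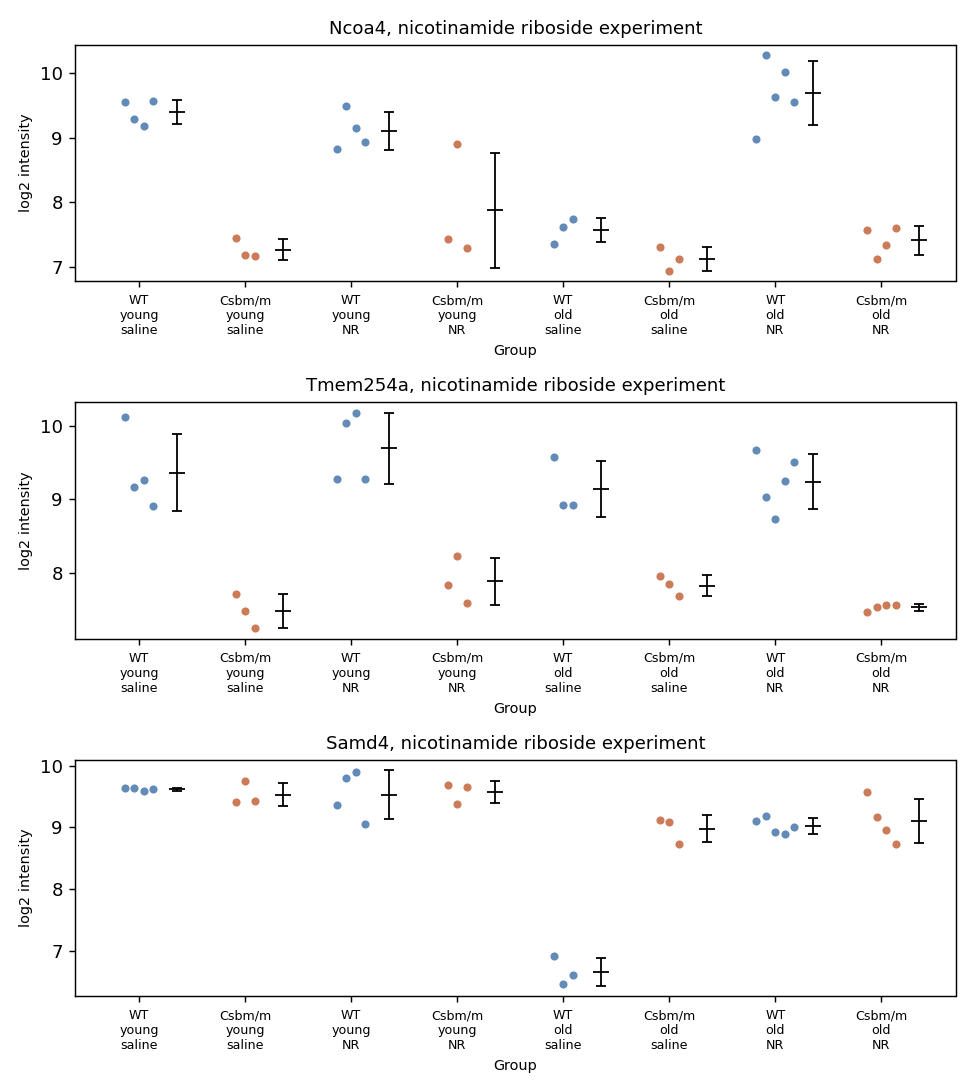
Log2 levels (y axis) of Ncoa4, Tmem254a and Samd4 in the 8 groups of the NR experiment (x axis), with points for arrays (blue WT, orange Csbm/m) and a black bar for mean ± SD. Samd4 is 6.66 ± 0.23 in old WT on saline and 8.98 to 9.62 elsewhere, Ncoa4 is low there too (7.57 ± 0.19), and Tmem254a is low in Csbm/m groups alone (7.49 to 7.89).

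Of the 39 lists, 9 were called in none of the 23 planned comparisons. Genes of NAD synthesis and use had a smallest adjusted p of 0.119, sirtuins and PARPs 0.163, nucleotide excision repair 0.0622, base excision repair 0.118, RNA polymerase I and ribosome biogenesis 0.0951, inhibitory interneurons 0.131, endothelial cells and pericytes 0.0555, the circadian clock 0.0535 and insulin, IGF and growth hormone signalling 0.138. The 23 comparisons gave 203 list calls, 142 higher and 61 lower, of which 6 held with an estimated correlation: microglia and red blood cells with caloric restriction in Csbm/m, microglia, complement and lysosome by genotype in young saline mice, and lysosome by genotype in old saline mice.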

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

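Of the tests in this part, those of the array background, of NR as the cause of the chromosome 14 calls and of the other splits were written before their results were seen, and all others only after. Patterns are weighed first.

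Many genes separated Csbm/m from WT on the standard diet (1935) and few on caloric restriction (40), where all arrays lie in 1 batch. Over the 1935 genes the shift of WT arrays on caloric restriction against WT on the high-fat diet, which crosses the batches, was 0.541 of the shift between the genotypes on resveratrol (jackknife SE 0.163). The shift between the genotypes inside 1 batch was 0.330 of it (SE 0.0932). Either could thus hold over 0.5 of the shift within 2 SE. Which of them set the count cannot be told, also since no WT array on another diet lies in the first batch.

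Many genes separated the high-fat from the standard diet in Csbm/m (1723). Each of 4 explanations weighed as its main source missed what it needs by over 2 SE. This excludes all but a change of the high-fat diet alone. Such a change needs over 0.5 of the shift to be left against resveratrol, and 0.00499 was (jackknife SE 0.132). Only 1 resveratrol array lies on the standard-diet side of the batch and 5 on the other, against 3 and 4 high-fat arrays. A shift between the sides in resveratrol was not tested and could hide a change of the high-fat diet alone. The array background needs over 0.5 and predicted 0.194 (SE 0.0741). Standard-diet libraries set apart need under 0.25 to be left against caloric restriction, and 0.689 was (jackknife SE 0.196). All 6 standard-diet and all 6 restricted arrays of Csbm/m lie on 1 side of the batch. Some libraries of each had a low granule cell level, so a source shared by these groups is not excluded. An array run needs high-fat arrays on the side of the standard-diet arrays to shift by under 0.25 of a reference. That reference is the shift of resveratrol arrays on the other side, and those high-fat arrays shifted by 0.756 of it (jackknife SE 0.208). A change shared by the high-fat diet and resveratrol was not tested. It stays open, as do a change of the high-fat diet alone and lesser shares of the other sources. The bounds first written, changed after the results had been seen, are met by all 4 values but by none of them with 2 SE.

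Genes of chromosome 14 led the genotype comparisons and those with old WT mice on saline. In the batch-matched genotype comparison 6 of 38 called genes lie on chromosome 14 (exact hypergeometric p = 0.00169), which would fit a strain variant near Ercc6 carried along with the mutation, and in the NR comparison of old WT 7 of 8 do (exact hypergeometric p = 3.3e-10), which would fit another strain variant in the 3 saline libraries. Csbm/m mice like those of the other groups, under a WT label, are excluded. These libraries lie 0.107 of the way from WT to Csbm/m by the median of 3 marker genes (highest single library 0.281). Gpnmb was 8.04 against 11.44 in old Csbm/m. The markers Tmem254a and Entpd4 lie 149 genes before and 1132 genes after Ercc6, and Thap4 lies on chromosome 1. Arhgap22 (8.00 against 8.11) and Ncoa4 (7.57 against 7.12), the called genes nearest to Ercc6, lie near Csbm/m in these libraries. No probe reads Ercc6, so the mutation beside other flanking genes is not excluded, and samples from outside the study stay open. NR acting alike in all groups is excluded as the cause: the highest median change of the same genes in the other 3 treated groups was 0.122, against 1.25 in old WT. In those 3 pairs Samd4 was not low on saline (8.98 to 9.62). An effect of NR in old WT alone was therefore not tested and stays open. No variant was read from sequence.

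For each count the arrays were divided in other ways. Chance counted as excluded where a share under 0.05 of the splits gave as many genes, not adjusted over the 23 counts. By that rule NR over all groups passes below, but another split gave more genes. Samd4 and Ogfod3, among its 3 genes, owe their call to old WT, where chance could not be excluded. Nothing is drawn from that count. Chance could be excluded for the genotype on the standard diet (2 of 100 splits as large, the real one included; real 1935, highest other 2249), on the high-fat diet (1 of 100; 1624, 1105) and over all diets (1 of 100; 4856, 588), for the high-fat diet in Csbm/m (1 of 100; 1723, 1399), caloric restriction in WT (1 of 35; 576, 1), resveratrol in Csbm/m (1 of 100; 1298, 343), the high-fat diet by genotype (1 of 100; 61, 1), caloric restriction by genotype (2 of 100; 245, 318), the genotype in young saline mice (1 of 35; 6, 1) and NR over all groups (2 of 100; 3, 4). It could not be excluded for the high-fat diet in WT (2 of 35; 28, 32), caloric restriction in Csbm/m (12 of 100; 11, 1415), resveratrol by genotype (6 of 100; 1, 449), age in WT (2 of 35; 104, 134), age by genotype (6 of 100; 4, 673), NR in old Csbm/m (4 of 35; 1, 1), NR in old WT (8 of 56; 8, 2038) and NR by genotype in old mice (7 of 100; 4, 747). With a real count of 0 every split is as large, so nothing follows for resveratrol in WT (100 of 100; 0, 165), NR in young WT (35 of 35; 0, 11) and NR in young Csbm/m (10 of 10; 0, 1). The splits were too few for the genotype in old saline mice (1 of 10; 44, 2) and age in Csbm/m (1 of 10; 255, 1). Title numbers pair the arrays in 3 comparisons, and of the splits that part all 3 pairs 1 of 8 was as large for NR in old WT, 1 of 8 for NR in old Csbm/m and 1 of 4 for the genotype in old saline mice, the real one each time with 0 genes in every other, too few for a share under 0.05. The split with 1415 genes sets caloric restriction replicates 1 to 3 and standard-diet replicates 2, 5 and 6 of Csbm/m against the rest, that with 2249 sets standard-diet replicates 1, 3 and 4 of Csbm/m and 1 of WT apart, and that with 2038 joins old WT saline replicates 1 and 2 with NR replicates 1, 4 and 5, which keeps 2 of the 3 pairs together, so the samples hold a structure that is not their group.

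Single samples stood far from the rest of their group in 12 of 244 values tested, where chance gives about 5 percent. Clec7a was 5.78 in Csbm/m on caloric restriction replicate 6 (others 6.50 to 6.92). Pdk4 was 9.58 in Csbm/m on the standard diet replicate 3 (others 7.71 to 8.28). Tmem254a was 10.22 in WT on the high-fat diet replicate 3 (others 9.74 to 9.77). Nmrk1 was 6.36 in NR-treated old Csbm/m replicate 1 (others 6.67 to 6.70) and 6.96 in young WT on saline replicate 2 (others 6.34 to 6.42). The brainstem list level was -0.18 in Csbm/m on resveratrol replicate 2 (others -0.80 to -0.66) and -2.36 in WT on the high-fat diet replicate 1 (others -0.97 to -0.76). The choroid plexus level was 0.15 in WT on the high-fat diet replicate 4 (others 0.72 to 0.80). In WT on the standard diet replicate 1 the Purkinje cell level was 0.12 (others 1.29 to 1.43) and the endothelial level 0.0398 (others 0.22 to 0.25). The granule cell level was 1.99 in NR-treated old Csbm/m replicate 4 (others 1.79 to 1.82), and the oligodendrocyte precursor level 0.35 in NR-treated old WT replicate 3 (others 0.91 to 1.07).

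A test of the difference between genotypes passed for 61 genes with the high-fat diet, 245 with caloric restriction, 1 with resveratrol, 4 with age and 4 with NR in old mice.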

How the results depend on the processing

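Against the main values 187 alternatives stayed on their side or within 1.5 times, 73 moved further, 3 gained a call and 9 lost it, and the cause was not tested unless stated. The stricter filter, the fit without low-weight arrays, caloric restriction as control or genotype pair, and the fit without chromosome 14 were chosen after the data had been seen. The fits meant for Ercc6, such as another choice of its probe, were not run. With a median of 58.2% of probes detected in the diet and 54.8% in the NR experiment, genes near background give bounds only, and 27.3% to 56.1% of genes shifted by 0.5 log2 were called in simulation. Of 332 calls of named genes 68 were lost without low-weight arrays, 44 with the deposited score and 34 without the detection filter. Every setting kept 1 of 13 for the high-fat diet in WT, 6 of 16 for the genotype in old saline mice and 25 of 49 for resveratrol in Csbm/m. Cox4i1 (genotype over all diets) changed sign with the deposited score.

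Without normexp the counts were 59 (high-fat diet in WT), 4 (resveratrol by genotype), 2 (age by genotype), 0 (NR in old Csbm/m) and 1 (NR over all groups). With the deposited score they were 341 (high-fat diet in WT, 48.7% higher against 82.1%), 3 (resveratrol by genotype), 29 (genotype, old saline), 2 (age by genotype), 0 (NR in old Csbm/m) and 1 (NR over all groups), and of the called genes 71.2% were higher for the genotype on the high-fat diet (58.7% in the main fit) and 51.7% for the high-fat diet by genotype (24.6%). Without the detection filter they were 2848 (genotype, high-fat diet), 196 (high-fat diet in WT), 897 (caloric restriction in WT), 103 (high-fat diet by genotype), 371 (caloric restriction by genotype), 3 (genotype, young saline), 167 (age in Csbm/m) and 2 (NR in old Csbm/m). With every detected probe they were 1972 (resveratrol in Csbm/m), 0 (resveratrol by genotype), 179 (age in WT) and 457 (age in Csbm/m), and with trend and robust 6 (resveratrol by genotype) and 1 (NR over all groups).

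Array weights gave 2992 (genotype, standard diet), 89 (high-fat diet in WT), 45 (caloric restriction in Csbm/m), 1273 (caloric restriction in WT), 610, 623 and 584 (high-fat diet, caloric restriction and resveratrol by genotype), 57 and 150 (genotype, young and old saline), 1245 and 1826 (age in WT and Csbm/m), 9 (age by genotype), 4 (NR in young Csbm/m), 58 (NR in old Csbm/m), 4 (NR in young WT), 166 (NR in old WT, 24 higher and 142 lower), 13 (NR by genotype) and 6 (NR over all groups). The stricter filter gave 951 and 608 (genotype, standard and high-fat diet), 13 (high-fat diet in WT), 124 (caloric restriction in WT), 49 (caloric restriction by genotype), 17 (genotype, old saline) and 0 (NR in old Csbm/m). Without low-weight arrays there were 2897 (genotype, high-fat diet), 156 (high-fat diet in WT), 3 (resveratrol in WT), 536 and 498 (high-fat diet and resveratrol by genotype), 13 (genotype, old saline), 255 (age in WT), 13 (NR in old WT) and 1 (NR over all groups). Without chromosome 14, which tests fewer genes, there were 0 (genotype, young saline), 21 (genotype, old saline), 0 (age by genotype), 1 (NR in old WT), 0 (NR by genotype) and 0 (NR over all groups). The batch-matched genotype pair gave 40 in place of the standard diet, high-fat diet and all-diet counts, and caloric restriction as control 224 (high-fat diet) and 206 (resveratrol) in Csbm/m. Of 203 list calls 6 held with an estimated correlation, and fry made 57 calls of its own, not all among the 203. Shared controls gave correlations of -0.53 (high-fat diet), -0.44 (caloric restriction) and -0.47 (resveratrol) with the genotype change, and the batch-matched pair -0.56 and -0.60 (high-fat diet and resveratrol).

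With the replicate number as a block the counts were 10 (high-fat diet in WT), 37 (high-fat diet by genotype), 2 (resveratrol by genotype), 3 (genotype, young saline) and 1 (NR over all groups), and with the number in the sample name as block 1, 8 and 0 for the first 3 of these. In the 3 comparisons whose numbers pair the arrays, the block moved the counts from 44 to 35, 1 to 1 and 8 to 9, and changed no other call. In all other comparisons the arrays share only a number.

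With single libraries left out, the counts ran from 1122 (without WT standard-diet replicate 4; 1152 without replicate 3) to 2483 for the genotype on the standard diet, 870 (WT high-fat 1) to 2140 on the high-fat diet and 4325 to 5245 over all diets. For the high-fat diet they ran from 876 (Csbm/m standard diet 3; 1113 without Csbm/m high-fat 6) to 1985 in Csbm/m, and in WT from 2 (high-fat 1) over 4 (standard diet 1), 9 (standard diet 3), 11 (standard diet 4) and 17 (high-fat 4) to 86 (high-fat 2). For caloric restriction they ran from 6 (Csbm/m restriction 2 or 5) over 18 (standard diet 1) to 28 (standard diet 4) in Csbm/m and 405 to 547 in WT, and for resveratrol from 795 (standard diet 3; 821 without resveratrol 2) to 1403 in Csbm/m and 0 to 2 (resveratrol 1; 1 without standard diet 3) in WT. By genotype they ran from 9 (WT high-fat 1) to 318 (WT standard diet 1) for the high-fat diet, with 13, 22 and 25 without WT standard diet 3, 4 and 2, 27, 33, 35 and 37 without Csbm/m high-fat 2, 6, 3 and 5, 28, 36, 96 and 126 without Csbm/m standard diet 6, 2, 1 and 4, and 122 without WT high-fat 4. They ran from 202 to 270 for caloric restriction and from 0 (Csbm/m resveratrol 1 to 5, Csbm/m standard diet 6, WT resveratrol 2 to 5, WT standard diet 2 or 3) to 119 (WT standard diet 1) for resveratrol, with 2 without Csbm/m standard diet 2 or WT standard diet 4, 5 without Csbm/m standard diet 1 or 4, 7 without its replicate 3, 31 without Csbm/m resveratrol 6 and 82 without WT resveratrol 1.

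In the NR experiment the counts ran from 2 (Csbm/m saline 3) to 5 for the genotype in young mice, with 3 without Csbm/m saline 1 or 2 or WT saline 2, 3 or 4, and from 12 (WT saline 3) to 63 in old mice, with 18 without WT saline 2 and 22 and 24 without Csbm/m saline 3 and 2. For age in WT they ran from 19 (old 2) to 185 (old 1), with 46 without old 3 and 161, 37, 36 and 29 without young 1, 2, 3 and 4. For age in Csbm/m they ran from 14 (young 2) to 459 (old 1), with 17 without young 3 and 81 and 29 without old 2 and 3. For age by genotype they ran from 2 (old Csbm/m 2, old WT 2 or 3, young Csbm/m 2 or young WT 2) to 5. For NR they ran from 0 to 1 (saline 2) in young Csbm/m, from 0 (NR 2 or 4, saline 2 or 3) to 13 (saline 1) in old Csbm/m, from 0 to 0 in young WT, from 7 to 207 (NR 1) in old WT, from 4 to 6 by genotype and from 1 to 4 over all groups.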

Other observations

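Of the tests in this part, the comparisons against caloric restriction and of NR-treated old mice were chosen only after the data had been seen. In Csbm/m the high-fat diet (7 arrays) against caloric restriction (6 arrays) raised Fcrls by 1.53 ± 0.21 (adjusted p = 0.00016, 7 of 7 arrays above all controls), Gpnmb by 1.19 ± 0.17 (adjusted p = 0.000176, 7 of 7), the class II gene H2-Aa by 1.21 (adjusted p = 0.000399) and Clec7a by 1.16 ± 0.19 (adjusted p = 0.000749, 7 of 7, though its 3 other probes moved by -0.15 to 0.63). Alas2, the first enzyme of haem synthesis in red cells, fell by 2.05 (-2.05, adjusted p = 0.0228), Slc4a1 by 1.77 ± 0.46 (-1.77, adjusted p = 0.0347) and Vgf by 1.28 (-1.28, adjusted p = 0.0111). The actin regulator Cfl1 also fell (adjusted p = 0.000399). Acat1 fell by 0.73 ± 0.12 (-0.73, adjusted p = 0.000713) and Oxct1 rose by 0.24 ± 0.06 (adjusted p = 0.0408), each the reverse of its change with caloric restriction against the standard diet (0.58 and -0.32), over the same 6 restricted arrays. Microglial genes rose in 7 of 22 cases (15 adjusted over the list alone, camera adjusted p = 8.07e-15, and 0.0364 as an adjusted p with an estimated correlation). With resveratrol against caloric restriction they rose in 11 of 22 (14 adjusted over the list alone, adjusted p = 4.8e-16, and 0.025 as an adjusted p with an estimated correlation), with Fcrls at 1.45 ± 0.22 and Gpnmb at 1.36 ± 0.18. Astrocyte, oligodendrocyte, Purkinje cell, granule cell and choroid plexus lists lay higher there too and the red blood cell list lower, each lost with an estimated correlation (0.0955 as the smallest adjusted p). For the high-fat diet against caloric restriction, Purkinje cell, granule cell, choroid plexus, meningeal and red blood cell lists were called as well. Their leading genes included Ebf1 (1.16), Lum (0.75), and Neurod1 (1.31) and Clic6 (1.09), which did not pass singly.

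In NR-treated old mice (4 Csbm/m against 5 WT arrays) 7 genes separated the genotypes. Gpnmb rose by 2.48 ± 0.35 (adjusted p = 0.000545), and Ncoa4 fell by 2.28 (-2.28, adjusted p = 1.57e-05) and Tmem254a by 1.70 (-1.70, adjusted p = 0.000233). Ncoa4 thus separates the genotypes among treated old mice, where WT stands at 9.69 ± 0.50 (n = 5), while on saline old WT stands at 7.57 ± 0.19 (n = 3) and old Csbm/m at 7.12 (n = 3). Along chromosome 14 Ncoa4 lies 10 genes before Ercc6 and Arhgap22 14 genes after it, Tmem254a and Plac9a 149 and 150 genes before it, and Samd4, Lgals3, Apex1, Ang, Abhd4 and Psmb5 279, 294, 382, 402, 692 and 710 genes after it.

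The level of the granule cell list was 1.31 ± 0.89 in Csbm/m on the standard diet (n = 6), 1.61 ± 0.86 on caloric restriction (n = 6), 2.09 ± 0.26 on the high-fat diet (n = 7) and 2.07 ± 0.19 on resveratrol (n = 6). In WT it was 1.56 ± 0.75 on the standard diet (n = 4), 2.21 ± 0.18 on caloric restriction (n = 4), 2.19 ± 0.25 on the high-fat diet (n = 4) and 2.07 ± 0.25 on resveratrol (n = 5). The choroid plexus level was -0.90 ± 0.85 in Csbm/m on the standard diet and 0.11 ± 0.89 on the high-fat diet. In the NR experiment the brainstem level was -1.87 ± 0.86 in young WT on saline (n = 4) and -0.85 ± 0.81 in young WT on NR (n = 4), and -0.14 ± 0.15 in old Csbm/m on saline (n = 3) and -0.78 ± 0.36 on NR (n = 4).

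The raw background was 76.4 ± 3.80 in Csbm/m on the standard diet, 75.6 ± 2.35 on caloric restriction, 71.6 ± 2.36 on the high-fat diet and 66.1 ± 3.43 on resveratrol. In WT it was 67.3 ± 1.23 on the standard diet and 58.9 to 59.2 on the 3 others.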
